A study of Homo sapiens with 6 samples.

How the data were processed

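RNA was measured in WI-38 cells, a human diploid fibroblast strain derived from fetal lung, at a population doubling level (PDL) of 20. Cultures received 50 nM of a control miRNA or of a precursor mimic of miR-340-5p and were harvested 4 days after transfection, per the labels. Each group held 3 libraries, numbered 1 to 3 in the labels. Nothing in the labels says whether the 3 libraries of a group came from separate transfections, so the p-values measure the spread between these libraries, which may be partly technical. Ribosomal RNA was depleted from total RNA and libraries were made with a stranded (dUTP) kit, per the labels' protocols, so that transcripts without a poly(A) tail, such as replication-dependent histone mRNAs, were retained.

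The authors deposited raw counts per gene, as whole numbers over 57773 Ensembl gene identifiers, in 1 table per library. STAR, featureCounts 1.4.6-p5, DESeq2 1.26.0 and the hg19 genome build are named in the submitters' processing notes, without their settings. The gene annotation, the strand setting of the counting, the treatment of reads that map to several places and whether reads or fragments were counted are not given in the sources used here. Counts of genes with near-identical copies, which include histone, ribosomal protein and small nuclear RNA genes, are therefore uncertain, as are those of overlapping genes. Across 1026 pairs of tested genes in which one is named as the antisense RNA of the other, the log2 fold changes had a Pearson r of 0.783 and a Spearman rho of 0.697 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give; across genes, which are not independent replicates). Whether the strands were kept apart is not known, and changes of antisense genes are not interpreted.

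Gene symbols came from a table of Ensembl identifiers and from GENCODE release 29. A symbol was found for 39880 of the 57773 identifiers (69.03%) and for 19177 of the 24138 tested. Gene classes, transcript sequences and 3' UTRs were also those of GENCODE 29, which is built on GRCh38 and not on the build of the counts. It served for names, classes and sequence searches, and every coordinate printed is a GRCh38 coordinate.

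Totals ran from 61782033 to 81042703 counts per library. In CPM (counts scaled to a common library total), 1 count therefore corresponds to between 0.0128 and 0.016. Counting error weighs more in genes with few counts, and it was not compared with the spread between libraries gene by gene. Genes were kept with the filterByExpr function of edgeR 4.0.16 (R 4.3.3), which left 24138, of which 14459 code for proteins. Counts were scaled by the trimmed mean of M values (TMM) and tested with edgeR's quasi-likelihood F test, mimic against control, with no further term in the model. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and a gene is said to rise, fall or change at an adjusted p under 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of F. Levels are given as TMM-scaled CPM, mean ± SD over the 3 libraries of a group. For a gene with no count in a group, the fold is a lower bound computed against 3 counts over the group. For a gene with 1 to 3 counts in a group, the ratio is given with its exact 95% counting interval, which covers counting error only.

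There were 34 gene lists, written before the data were examined and matched by symbol. Each list with at least 5 tested members was tested with camera (limma 3.58.1) on the same counts, with a preset correlation between genes of 0.01 and adjustment over the 34 lists. The same test with an estimated correlation, and fry, were alternatives. Members were counted after adjustment over all genes and after adjustment over the list alone. LBR was left out of the nuclear envelope, G2/M and cholesterol lists and of the list of reported miR-340-5p targets. The list of reported miR-340-5p targets was written from memory. Genes named in the text are LBR, the 10 protein-coding genes with the largest rise and the 10 with the largest fall that passed the test, had a mean of at least 1 CPM in the higher group and no overlap between the groups' libraries, and up to 4 members with the smallest p of each list. A few others are named as chosen after their values were seen, and some members that the rule takes are not reported here.

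For the seed analysis, the 3' UTR of the transcript with the longest annotated 3' UTR was searched for CTTTATA, the match to bases 2 to 8 of miR-340-5p (UUAUAAAGCAAUGAGACUGAUU). Tested protein-coding genes with a match were compared with genes lacking even the 6-base match TTTATA, by the difference in median log2 fold change. The comparison used a two-sided permutation test over genes with 100000 resamples, a bootstrap interval from 2000 resamples, and 104 rearrangements of the same 7 bases. Genes are not independent replicates, and that p describes genes, not cultures.

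Alternatives fixed before the data were examined were DESeq2 size factors, no filter on low counts, a filter of 1 CPM in 3 libraries, a replicate block, DESeq2 1.42.0 and limma-voom as tests, a log2 fold change of at least 1, protein-coding genes alone, leaving out each library in turn, and several forms of the seed search. Added after the data were seen were a correction for the trend of each library's values on transcript GC content, the removal of small structured RNAs, and the seed comparison matched on 3' UTR length and GC with each library left out. Transcript GC content was known for 22771 of the 24138 tested genes (94.34%). The replicate numbers were not used to pair libraries.

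The steps were tested on simulated data. In counts for 24138 genes drawn with the libraries' own means, depths and dispersions, 200 genes were changed. The test recovered 35.8% of those changed by 0.5 on the log2 scale, 64.2% of those changed by 1 and 92.4% of those changed by 2, and 7.45% of all calls were false. In the data 9696 genes changed, far more than in the simulation. These shares depend on that number, so they need not hold for the real test. A shift of -0.5 put on the G1/S list was recovered as a median of -0.51, and 1 other list passed. With the GC trends of the real libraries added within each group, calls numbered 104 without the GC correction, of which 1.92% were false, and 144 with it, of which 6.25% were false. A shift of -0.2 put on the genes with a seed match, among 14162 genes, came back as -0.18. Statistics over genes used numpy, scipy and pandas under Python 3.11.15.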

Results

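The series compared RNA from WI-38 fetal lung fibroblasts 4 days after transfection with 50 nM of a control miRNA or of a precursor mimic of miR-340-5p, with 3 libraries in each group. Its title ties miR-340 to suppression of LBR, to chromatin, to cell senescence and to the killing of senescent cells, and the comparison asks which transcripts differ when the miRNA is raised. The control libraries held 81042703, 71354290 and 64247495 counts, and the mimic libraries 69985076, 76101550 and 61782033. Principal component 1 of log2 CPM carried 66.3% of the variance and separated the groups, and component 2 carried 11.9% and spread the control libraries. Mitochondrial transcripts took 2.98% to 3.37% of counts in the control libraries and 2.41% to 2.66% in the mimic libraries. Small structured RNAs took 6.99% to 8.94% and 9.08% to 9.77%. At equal totals, between 31522 and 31702 identifiers were detected in the control libraries and between 32043 and 32506 in the mimic libraries. Differences between the control libraries followed transcript GC content, with a Spearman rho over 12091 genes of -0.725 to -0.879, against -0.34 to 0.247 between mimic libraries and 0.12 between the group means. Every pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 7.31 or more.

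LBR, the lamin B receptor, fell with the mimic. This protein of the inner nuclear membrane binds lamin B and heterochromatin and has sterol reductase activity. LBR (ENSG00000143815; GRCh38 chromosome 1, 225401502 to 225428925, minus strand) measured 46.9 ± 4.83 CPM (SD, n = 3) in the control group and 12.2 ± 1.399 CPM (SD, n = 3) in the mimic group. It fell by 1.95 on the log2 scale (SE 0.11), which is 3.86-fold lower, with an edgeR adjusted p of 1.12e-07 and no overlap between the groups. Its 3' UTR of 1801 bases holds 2 matches to bases 2 to 8 of miR-340-5p. The 8-base match CTTTATAA begins at GRCh38 chromosome 1, 225402417, reading toward lower coordinates, with its 7-base core at 225402411 to 225402417. The other match, CTTTATA, lies at 225402204 to 225402210, and the matches span bases 886 to 892 and 1093 to 1099 of the UTR. Over all tested genes the median log2 fold change was 0.01, a value that TMM scaling holds near 0.

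The transcriptome changed broadly. TMM scaling places the centre of the log2 fold changes near 0, so the balance of higher and lower genes is largely set by it. A shift in the total amount of RNA per cell could not be seen. Of 24138 tested genes, 9696 changed, with 4737 higher and 4959 lower in the mimic group. Among them, 3120 changed by at least 1 on the log2 scale, of which 1682 were higher and 1438 lower. The groups' libraries did not overlap for 12322 genes (51.05% of those tested), where chance alone gives 10%. By class, 7374 of 14459 protein-coding genes changed (3477 higher, 3897 lower), as did 1273 of 4752 long noncoding genes (719 higher, 554 lower), and 498 of 2834 pseudogenes. Long noncoding genes include antisense RNAs, whose counts cannot be told from those of their partners where strands were not kept apart. Over 1026 pairs of a gene and its named antisense RNA, log2 fold changes had a Pearson r of 0.783, and BMF, ELN, ACTA2 and GDF5 are among the genes with such a partner.

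Several of the largest rises were in genes close to silence in the control libraries. NPY, a neuropeptide (GRCh38 chromosome 7, 24284163 to 24291865), had 0 counts in the control group and 319 in the mimic group, at least 110.8-fold higher against 3 counts over the group. BRINP3 went from 0 to 281 counts, at least 97.6-fold higher. PCDH19, a protocadherin, went from 2 to 393 counts (95% counting interval of the ratio 56.3 to 1697), PLCH1, a phospholipase C, from 2 to 286 (40.9 to 1236), and FGF13 from 2 to 272 (38.9 to 1176). ADGRL3, an adhesion receptor of the latrophilin family, rose from 0.0589 ± 0.0606 to 9.93 ± 0.77 CPM and PARM1 from 0.152 ± 0.0267 to 18.9 ± 1.19 CPM. PDK4, a kinase that inhibits pyruvate dehydrogenase, rose from 0.0287 ± 0.0279 to 3.41 ± 1.07 CPM, ZNF385B from 0.017 ± 0.0295 to 2.01 ± 0.58 CPM, with its 4 control counts all in control replicate 1, and ISM1 from 0.112 ± 0.0487 to 10.1 ± 1.07 CPM (SD, n = 3 for each). In all, 24 protein-coding genes went from a mean under 0.1 CPM to at least 1 CPM, all past the threshold, and 0 tested protein-coding genes went the other way by the same limits.

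Among the 10 named genes with the largest falls were PTX3, GDF5, PAK6 and SGO1. PTX3, pentraxin 3 (GRCh38 chromosome 3, 157436789 to 157443628), fell by 3.26 on the log2 scale (SE 0.09), from 94.2 ± 2.69 to 9.81 ± 0.88 CPM (SD, n = 3). GDF5, a growth factor of the bone morphogenetic protein family, fell by 3.21 (SE 0.16), the kinase PAK6 by 3.16 (SE 0.33) and CDA, cytidine deaminase, by 3.07 (SE 0.37). SGO1, which protects sister chromatid cohesion, fell by 3.09 (SE 0.20), the mitotic kinesins KIF20A and KIF14 by 2.99 (SE 0.09) and 2.84 (SE 0.21), and the spindle protein DLGAP5 by 2.90 (SE 0.17). CPA4, a carboxypeptidase, fell by 2.90 (SE 0.09). BUB1B-PAK6, a readthrough gene, fell by 3.09 (SE 0.19), but it shares exons with BUB1B and PAK6, so its level and that of PAK6 are uncertain. Adjusted p was 3.91e-05 or smaller for each of these 10 genes.

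**Figure D1:**
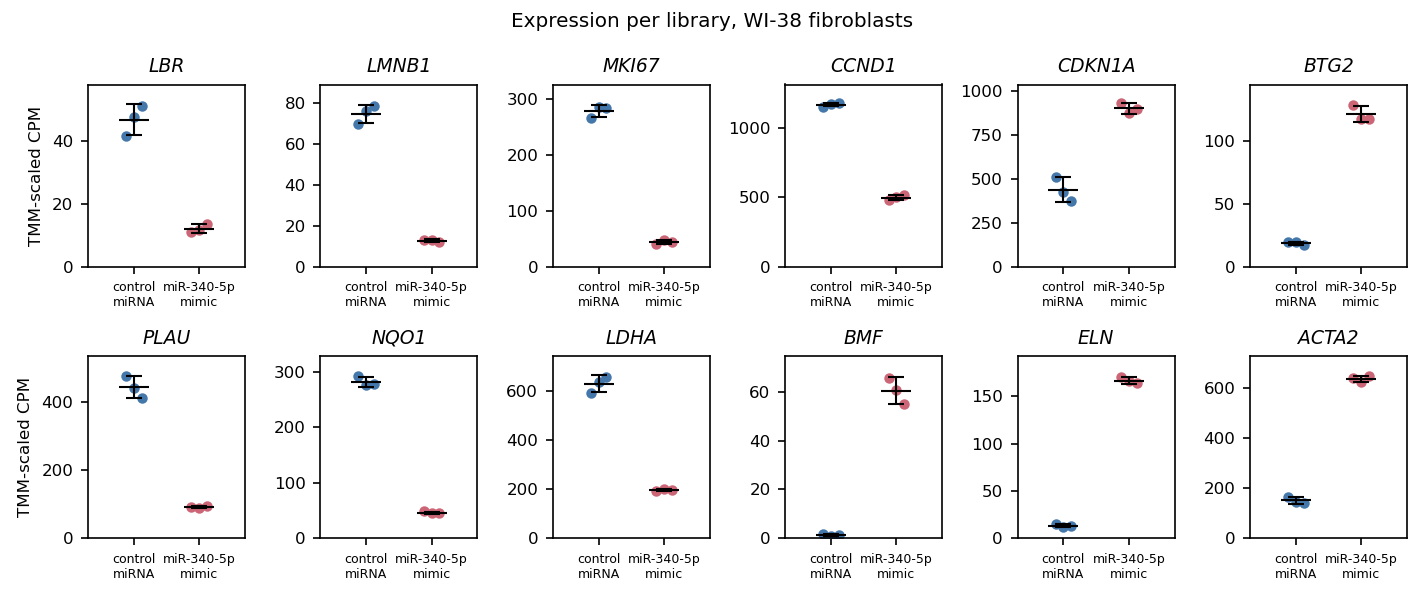
TMM-scaled CPM of 12 genes in each library, with 3 control miRNA libraries in blue and 3 miR-340-5p mimic libraries in red. Black bars mark the mean and SD of each group, every vertical axis starts at 0, and the groups do not overlap for any of these genes, with LBR at 46.9 CPM in the control group and 12.2 CPM in the mimic group.

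Genes of the dividing cell fell nearly throughout. Of 42 measured G1/S genes, 41 fell and 1 did not pass, with a median log2 fold change of -1.60. RRM2, a subunit of ribonucleotide reductase, fell by 2.55 (SE 0.09), CLSPN by 2.27 (SE 0.10), CDC6, which licenses replication origins, by 2.16 (SE 0.10), and the helicase subunit MCM4 by 1.89 (SE 0.08). Of 53 measured G2/M genes, 51 fell and 2 did not pass, with a median of -2.41. MKI67, which encodes the proliferation antigen Ki-67, fell by 2.64 (SE 0.08), from 278.9 ± 10.9 to 44.6 ± 3.47 CPM (SD, n = 3), and HJURP, a histone chaperone of centromeres, fell by 2.82 (SE 0.10). BIRC5, survivin, fell by 2.57 (SE 0.09) and TPX2, a spindle assembly factor, by 2.53 (SE 0.09). Of 20 cyclins, cyclin-dependent kinases and their activators, 17 fell and 1 rose. CCND1, cyclin D1, fell from 1166 ± 12.6 to 496.9 ± 18.2 CPM, CDK1 fell by 2.51 (SE 0.14), CCNB1 by 2.49 (SE 0.11) and CDK2 by 1.62 (SE 0.08). Camera's adjusted p was 8.71e-40 for G1/S, 1.72e-82 for G2/M and 2.98e-15 for cyclins and kinases, and 0.0357, 0.0182 and 0.0182 with an estimated correlation. The counts of members that fell were the same when adjusted over the list alone (41, 51 and 17).

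Centromere, chromatin and DNA repair genes fell along with them. Some of these genes also belong to the G1/S or G2/M list, among them CENPA, HMGB2, CBX5, HELLS, CHAF1B and BLM. The falls of these lists are therefore not wholly separate findings. Of 28 centromere and kinetochore genes, 22 fell and 0 rose, with a median of -1.46 and an adjusted camera p of 4.54e-20. ZWINT fell by 2.29 (SE 0.12), SPC24 by 2.19 (SE 0.10) and CENPA, the centromeric histone H3 variant, by 1.60 (SE 0.10). All 15 measured replication-dependent histone genes fell, with a median of -1.42 (adjusted p = 3.25e-29; adjusted p = 0.0518 with an estimated correlation). The linker histone H1-5 fell from 220.8 ± 7.80 to 39.8 ± 1.44 CPM and H1-3 from 81.4 ± 2.94 to 16.7 ± 1.00 CPM (SD, n = 3), while H2AC13 fell by 2.20 and H2BC13 by 2.06. This list had 32 members, of which 15 were matched, and histone copies are close in sequence. Of 24 heterochromatin and histone methylation genes, 17 fell and 2 rose, with a median of -1.06 (adjusted p = 1.23e-10). The chromatin assembly factors ASF1B and CHAF1A fell by 2.71 (SE 0.15) and 1.49 (SE 0.09), HMGB2 by 2.18 (SE 0.09), and the maintenance DNA methyltransferase DNMT1 by 1.22 (SE 0.08). Of 30 genes of homologous recombination and the Fanconi anaemia pathway, 24 fell and 1 rose, with a median of -0.84 (adjusted p = 3.06e-10; adjusted p = 0.0756 with an estimated correlation). FANCD2 fell by 2.37 (SE 0.11), BLM by 2.09 (SE 0.14), BRCA1 by 1.84 (SE 0.13) and FANCI by 1.72 (SE 0.11). Adjusted over the list alone, the same numbers fell in each of these 4 lists (22, 15, 17 and 24).

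Genes of the nuclear lamina and inner nuclear membrane fell as a list by camera with the preset correlation, but not with an estimated one. Of 21 measured members besides LBR, 14 fell, 2 rose and 5 did not pass, and adjusted over the list alone 14 fell and 2 rose. LMNB1, lamin B1, fell from 74.7 ± 4.39 to 12.8 ± 0.66 CPM (SD, n = 3), which is 5.84-fold lower. TMPO, which encodes LAP2, fell by 1.75 (SE 0.14), LMNB2 by 1.09 (SE 0.09) and SUN1, of the complex that links the nucleus to the cytoskeleton, by 0.95 (SE 0.07). TMPO is also a member of the G2/M list. The list's median was -0.42 (adjusted p = 0.000304; adjusted p = 0.0518 with an estimated correlation).

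**Figure D2:**
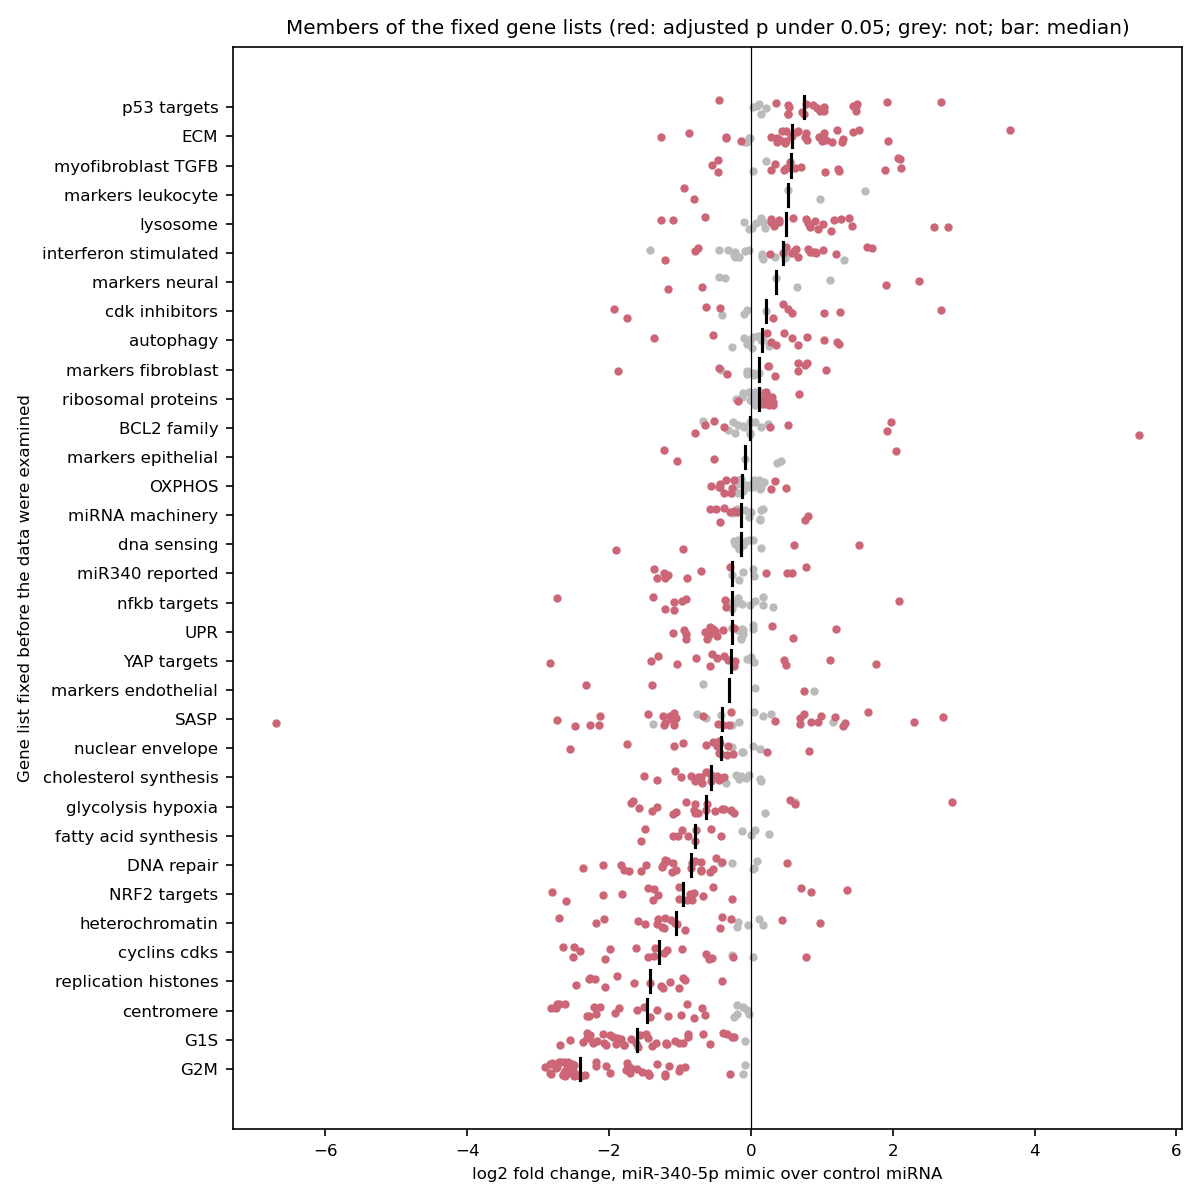
Log2 fold changes, mimic over control, of the measured members of the 34 gene lists, 1 point per gene, with lists ordered by median from high to low. Red points have an edgeR adjusted p under 0.05, grey points do not, and black bars are medians, which run lowest for the G2/M list at -2.41 and the G1/S list at -1.60. The point farthest left is CSF2, with 0 counts in the mimic group, and its place depends on the fit.

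Targets of p53 rose, and cell cycle brakes moved both ways. Of 25 genes activated by p53, 19 rose and 1 fell, also when adjusted over the list alone, with a median of 0.75 (adjusted p = 1.04e-12; adjusted p = 0.0237 with an estimated correlation). BTG2, an antiproliferative gene, rose 6.41-fold, from 18.9 ± 1.20 to 121.4 ± 6.28 CPM (SD, n = 3). FDXR and TP53INP1 each rose by 1.49 (SE 0.10), and PPM1D, a phosphatase that acts back on p53, by 1.49 (SE 0.09). Of 15 cyclin-dependent kinase inhibitors and other brakes, 7 rose and 4 fell (7 and 5 adjusted over the list alone), and the list did not pass (adjusted p = 0.214). CDKN1A, which encodes p21, rose 2.05-fold, from 438.5 ± 68.5 to 899.2 ± 29.4 CPM (SD, n = 3), while CDKN2C, which encodes p18, fell by 1.75 (SE 0.11) and RBL1, which encodes p107, by 1.93 (SE 0.12). CDKN2A, the gene of p16 and ARF, chosen after its value was seen, fell by 0.44 (SE 0.13, adjusted p = 0.017), from 18.7 ± 3.40 to 13.8 ± 0.16 CPM. Control libraries 1 to 3 stood at 22.1, 18.8 and 15.3 CPM, so the size of this fall depends on which control libraries are used.

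Among the BCL2 family and apoptosis genes, BMF, BCL2L11 and BBC3, which encode proapoptotic BH3-only proteins, had the largest rises, and the list as a whole did not pass. BMF rose 44.3-fold, from 1.36 ± 0.35 to 60.5 ± 5.36 CPM, BCL2L11, which encodes BIM, 3.92-fold (SE of the log2 value 0.19) and BBC3, which encodes PUMA, 3.78-fold (SE 0.17). Of 23 measured members, 5 rose and 4 fell, also when adjusted over the list alone. PMAIP1, which encodes the BH3-only protein NOXA and was chosen after its value was seen, fell by 0.65. The list's adjusted p was 0.197, with a median of -0.01 (down to -0.10, without control replicate 3), a mean of 0.28 and an upward test direction.

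Secreted factors tied to senescence moved in both directions, more often down. Of 44 measured genes of the senescence-associated secretory phenotype, 21 fell and 13 rose, with the same counts adjusted over the list alone and a median of -0.41 (adjusted p = 0.0263; adjusted p = 0.14 with an estimated correlation). PLAU, the urokinase plasminogen activator, fell from 444.5 ± 32.4 to 92.0 ± 2.22 CPM (SD, n = 3), MMP1, interstitial collagenase, fell by 2.47 (SE 0.10) and TNFRSF11B, osteoprotegerin, by 2.12 (SE 0.09), while IGFBP7 rose 3.15-fold (SE of the log2 value 0.08). Chosen after their values were seen, CXCL8 fell by 2.73 (SE 0.31), and IL6 had a log2 fold change of -0.17 (SE 0.14, adjusted p = 0.394). CSF2, with 0.182 ± 0.0293 CPM in the control group, had 0 counts in the mimic group and was at least 12.6-fold lower against 3 counts over the group, and with CSF2 at this bound the median was -0.41. The call of this list was lost with the filter of 1 CPM in 3 libraries, with a median of -0.29 and an adjusted p of 0.0941, and with no filter the median was -0.63 (adjusted p = 0.00385).

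NF-kB targets fell and interferon-stimulated genes rose as lists by camera with the preset correlation, but not with an estimated one. Of 21 NF-kB targets, 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.27 (adjusted p = 0.0147; adjusted p = 0.307 with an estimated correlation). TNFAIP2 fell by 1.38 (SE 0.14), ICAM1 by 1.21 (SE 0.11) and SOD2 by 0.98 (SE 0.09), and PTGS2, cyclooxygenase 2, was the member that rose, 4.24-fold from 0.975 ± 0.171 CPM. Of 37 interferon-stimulated genes, 16 rose and 3 fell (17 and 3 adjusted over the list alone), with a median of 0.45 (adjusted p = 0.0374; adjusted p = 0.298 with an estimated correlation). TRIM22 rose by 1.71 (SE 0.08), IFIT2 by 0.86 (SE 0.13) and LGALS3BP by 0.84 (SE 0.10), and OAS3 fell by 1.21 (SE 0.16). Without mimic replicate 3 that list had a median of 0.25 and an adjusted p of 0.0643. Among 15 measured nucleic acid sensing genes, 2 rose and 2 fell (1 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.386). RNASEH2A fell by 1.90 (SE 0.13) and CGAS, the cytosolic DNA sensor, by 0.95 (SE 0.14), while TLR3 rose by 1.52 (SE 0.24). IFIH1, which encodes the RNA sensor MDA5, rose by 0.61 (SE 0.22, edgeR adjusted p = 0.046), a call lost in 5 alternatives with adjusted p from 0.0567 to 0.14, with a value of 0.37 without control replicate 1.

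Matrix, contractile and lysosomal genes rose. Of 36 fibroblast matrix genes, 27 rose and 5 fell, also adjusted over the list alone, with a median of 0.58 (adjusted p = 8.11e-13; adjusted p = 0.0756 with an estimated correlation). ELN, elastin, rose 12.6-fold, from 13.3 ± 1.72 to 166.7 ± 3.50 CPM (SD, n = 3), TNC, tenascin C, rose by 1.53 (SE 0.07), THBS2 by 1.44 (SE 0.07) and COL8A1 by 1.29 (SE 0.06). Of 20 contractile and TGF-beta response genes, 15 rose and 3 fell (16 and 3 adjusted over the list alone), with a median of 0.56 (adjusted p = 2.76e-09; adjusted p = 0.13 with an estimated correlation). ACTA2, smooth muscle actin, rose 4.22-fold, from 151.4 ± 12.7 to 638.1 ± 11.5 CPM, PMEPA1 by 2.12 (SE 0.10), SMAD7 by 2.10 (SE 0.11) and TGFBI by 1.24 (SE 0.06) on the log2 scale. Of 30 lysosomal genes, 20 rose and 3 fell, also adjusted over the list alone, with a median of 0.50 (adjusted p = 4.26e-08; adjusted p = 0.14 with an estimated correlation). The cathepsin CTSF rose 6.84-fold, TPP1 2.61-fold, CTSA 2.41-fold and PSAP, prosaposin, 2.24-fold. GLB1, lysosomal beta-galactosidase, chosen after its value was seen, rose by 0.94 (SE 0.08). Of 20 YAP and TEAD targets, 12 fell and 4 rose, also adjusted over the list alone, with a median of -0.28 (adjusted p = 0.00261; adjusted p = 0.0853 with an estimated correlation). NT5E, the ectonucleotidase CD73, fell by 2.84 (SE 0.09), F3, tissue factor, by 1.41 (SE 0.07) and the receptor kinase AXL by 1.05 (SE 0.07), and FOXF2 rose by 1.11 (SE 0.09).

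Antioxidant, glycolytic and lipid synthesis genes fell. Of 20 NRF2 targets, 17 fell and 3 rose, also adjusted over the list alone, with a median of -0.96 (adjusted p = 6.82e-11; adjusted p = 0.0437 with an estimated correlation). NQO1 fell from 281.5 ± 8.62 to 46.3 ± 1.90 CPM (SD, n = 3), the cystine transporter SLC7A11 by 2.80 (SE 0.18), TXNRD1 by 1.45 (SE 0.06) and malic enzyme ME1 by 1.37 (SE 0.09). Of 25 glycolysis and hypoxia genes, 19 fell and 3 rose (19 and 4 adjusted over the list alone), with a median of -0.63 (adjusted p = 1.00e-09; adjusted p = 0.0756 with an estimated correlation). LDHA, lactate dehydrogenase A, fell 3.22-fold, from 629.9 ± 33.9 to 195.7 ± 3.50 CPM, the glucose transporter SLC2A1 by 1.67 (SE 0.10), ENO1 by 1.57 (SE 0.07) and PKM by 1.33 (SE 0.07) on the log2 scale. Of 14 fatty acid synthesis genes, 10 fell and 0 rose, also adjusted over the list alone, with a median of -0.79 (adjusted p = 4.31e-06; adjusted p = 0.0414 with an estimated correlation). The fatty acid elongase ELOVL6 fell by 1.56 (SE 0.11), the desaturases FADS1 by 1.03 (SE 0.08) and FADS2 by 0.97 (SE 0.10), and the desaturase SCD was 2.83-fold lower (SE of the log2 value 0.07). Of 25 cholesterol synthesis and sterol response genes, 16 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -0.57 (adjusted p = 5.98e-06; adjusted p = 0.0543 with an estimated correlation). ACAT2 fell by 1.07 (SE 0.08) and SQLE, squalene epoxidase, by 0.85 (SE 0.08). Of 27 unfolded protein response genes, 14 fell and 3 rose (16 and 3 adjusted over the list alone), with a median of -0.27 (adjusted p = 0.00261; adjusted p = 0.065 with an estimated correlation). The chaperones HSP90B1 and HSPA5 fell by 0.95 (SE 0.07) and 0.91 (SE 0.06) and TRIB3 by 1.10 (SE 0.12), and ATF3 rose by 1.21 (SE 0.13).

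With the preset correlation, 22 of the 34 lists passed, 17 downward and 5 upward. With an estimated correlation 8 passed, all among those 22: G1/S, G2/M, cyclins and kinases, centromere, heterochromatin, p53 targets, fatty acid synthesis and NRF2 targets. The cyclin, centromere and heterochromatin lists share members with the G1/S or G2/M list, so these are not independent results. By fry, which asks only whether a list's genes move on balance, 29 passed.

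Genes with a match to the miR-340-5p seed in their 3' UTR lay lower than genes without one. Among 14162 tested genes with an annotated 3' UTR, 2551 held the 7-base match and 6773 lacked the 6-base match. The median log2 fold change was -0.14 with a match and 0.03 without, a difference of -0.17 (bootstrap 95% interval -0.20 to -0.14; permutation p = 1e-05, the smallest that 100000 resamples can give). With a match, 944 genes fell (37.0%) and 494 rose (19.4%), against 1581 (23.3%) and 1677 (24.8%) without one. Medians were -0.12 for 1918 genes with 1 match, -0.18 for 467 with 2 and -0.33 for 166 with 3 or more. None of the 104 rearrangements of the same bases gave as low a difference, the lowest being -0.09. Median 3' UTR length was 2996 bases with a match and 644 without, and against genes without a match of like length and GC content the difference was -0.21 (bootstrap 95% interval -0.24 to -0.18, with 1681 of the 2551 genes in cells that could be matched). The size of the unmatched difference depended on single control libraries, at -0.28 without control replicate 1 and -0.07 without control replicate 3, and it was -0.10 with the GC correction. Matches to the seed of the other arm, miR-340-3p, gave a difference of -0.02 (permutation p = 0.406).

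Among genes reported elsewhere as miR-340-5p targets, listed from memory and with LBR left out, 8 of 17 fell and 4 rose, also adjusted over the list alone. Their median was -0.27 (camera adjusted p = 0.0116, and 0.419 with an estimated correlation). The median was -0.09 without control replicate 3 and -0.16 with the GC correction, and the list passed in both cases (adjusted p = 0.0157 and 0.00995). SKP2, a ubiquitin ligase subunit that targets p27, fell by 1.37 (SE 0.11) and has 2 seed matches, and CCND1 fell by 1.23 (SE 0.06) and has 1. EZH2 fell by 1.33 (SE 0.11) and NFE2L2, which encodes NRF2, by 0.90 (SE 0.08), and neither has a 7-base match in the 3' UTR searched. In the whole list, 10 of 17 genes have one, against 5 of 53 G2/M genes and 6 of 41 G1/S genes with a 3' UTR. Over all tested genes with a 3' UTR, 2551 of 14162 have one. Targets may have been reported because of such a match, so the share in their list is no separate test of the seed. CCND1 also belongs to the cyclin list and EZH2 to the heterochromatin list, so their falls are not separate findings. Among the 10 genes with the largest falls, KIF14 alone has a match. Among the 10 with the largest rises, FGF13 has 6, ADGRL3 has 3, and PCDH19 and PARM1 have 1 each. Their 3' UTRs are long, at 18119, 8166, 4633 and 3868 bases, while the longest among the 10 largest falls is 1891 bases. The contrast between rises and falls can therefore not be told apart from 3' UTR length.

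**Figure D3:**
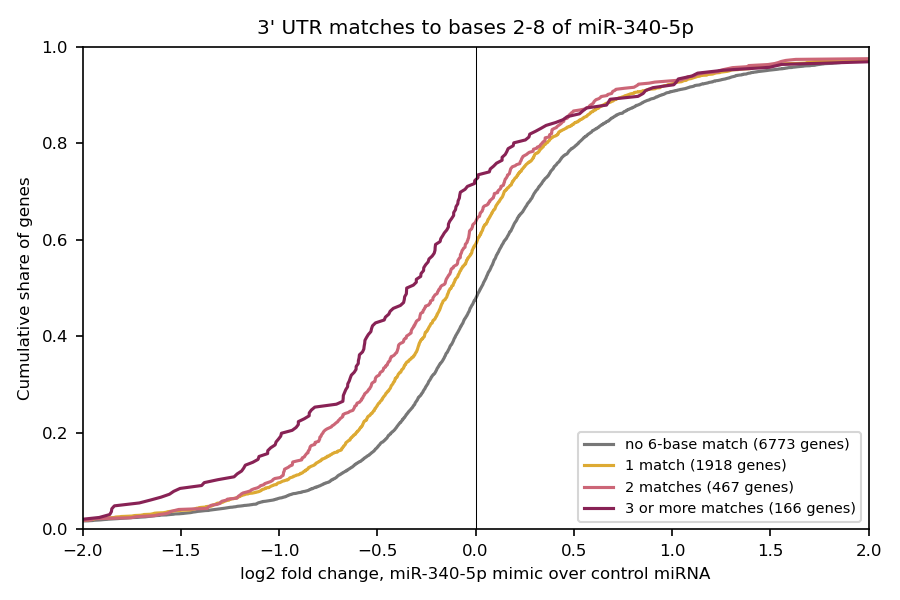
Cumulative share of genes by log2 fold change, mimic over control, for genes without the 6-base match (grey) and for genes with 1, 2 or 3 or more 7-base matches to the miR-340-5p seed in the 3' UTR. The curves move left with the number of matches, with medians of 0.03, -0.12, -0.18 and -0.33.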

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

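The GC correction, the removal of small structured RNAs and the matched seed comparison with single libraries left out were chosen only after the data were seen, and the other alternatives before the data were examined. Of 123 values of the 8 main results under alternatives, 118 kept their direction and side of the threshold, as did 2129 of 2137 values for named genes and 419 of 445 for single lists, by the direction of camera's test. The direction of that test changed only for the neural markers with the GC correction, which did not pass either way (median 0.33). Of the values of these alternatives, 7 list medians had another sign, all in the epithelial, endothelial and neural marker lists, which camera did not call. A minimum log2 fold change of 1 left 3120 genes (1682 higher, 1438 lower), fewer by construction. Camera with an estimated correlation left 8 lists. The estimate was -0.021 for the nuclear envelope list and -0.030 for the unfolded protein response list, both under the preset 0.01. A higher correlation between genes therefore does not explain the loss of those calls. With an estimated correlation, camera also takes its p from the degrees of freedom left between libraries, which are few here. With a preset one it does not. A call lost in that setting therefore need not mean a higher correlation between genes. How much of each loss came from this was not tested. Sites of the miR-340-3p arm gave a seed difference of -0.0155, and that arm is not the one the mimic was named for. Other counts of changed genes were 9683 with DESeq2 size factors, 10295 with no filter, 8901 with the CPM filter and 9757 with limma-voom. With protein-coding genes alone 7551 changed, without small structured RNAs 9610 and with the GC correction 11779. DESeq2 gave 9500, but was run on all genes with a count and not on the filtered ones. It gave an adjusted p for 31671 genes and none for 7618. Leaving out a library gave 7520 to 11839 genes, LBR values of -2.05 to -1.88, G1/S medians of -1.68 to -1.58, G2/M medians of -2.44 to -2.33, 21 to 23 lists and seed differences of -0.28 to -0.07. Same-numbered libraries showed little shared deviation (correlations of 0.0625, 0.0285 and 0.00363). With 3 libraries per group and a GC trend among the control libraries, such values do not exclude a pairing by number. With the replicate block 9824 genes passed, 9372 of them shared, LBR stood at -1.95 and no list changed its call. Among named genes, IFIH1 lost its call in 5 alternatives, EPCAM in 2 and RPS12 in 1. Genes named as chosen after their values were seen were not followed through the alternatives. Depth limits genes near 1 count, such as NPY and CSF2 in the group where they had none.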

Other observations

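The rearrangements' limits, the matched medians by number of matches, the matched difference with single libraries left out, the tests of neurons and of small structured RNAs, the GC correction and the splits of the libraries were chosen only after the results were seen, and the matched seed comparison itself was planned but its limits were set afterwards. Oxidative phosphorylation, ribosomal protein and miRNA machinery genes moved little as lists. Of 32 oxidative phosphorylation genes 9 fell and 3 rose, also adjusted over the list alone, with a median of -0.12 (camera adjusted p = 0.387). SDHB, of complex II, fell by 0.56 and ATP5F1B by 0.43, while NDUFB5 rose by 0.50 and NDUFA4 by 0.34. Of 40 ribosomal protein genes 13 rose and 1 fell (12 and 0 adjusted over the list alone), with a median of 0.11 (adjusted p = 0.158), which was 0.16 without control replicate 1 (adjusted p = 0.022) and 0.07 without control replicate 3. RPS19 rose by 0.68, RPS20 by 0.30 and RPS12 by 0.28, the last lost without mimic replicate 1 (adjusted p = 0.0565). Of 18 miRNA machinery genes 7 fell and 2 rose, also adjusted over the list alone, with a median of -0.14 (adjusted p = 0.677), which was -0.05 without control replicate 1. AGO2, which binds miRNAs, fell by 0.49 and PRKRA by 0.58, while TNRC6B, of the silencing complex, rose by 0.80 and PAN2, a deadenylase, by 0.76. Of 24 autophagy genes 10 rose and 2 fell, also adjusted over the list alone, with a median of 0.16 (adjusted p = 0.0543, and 0.0202 with no filter on low counts). The kinase gene ULK1 rose 2.38-fold, GABARAPL1 2.32-fold and GABARAP 1.58-fold, and SQSTM1, the cargo receptor p62, fell by 1.36.

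Among the 5 lists of cell type markers, none passed by camera, while fry, which does not compare a list with other genes, called the fibroblast (adjusted p = 0.00613), endothelial (0.0108) and neural (0.0436) lists. Of 17 fibroblast markers 7 rose and 3 fell (adjusted p = 0.214). COL1A2 rose from 3583 ± 334.7 to 6101 ± 272 CPM (SD, n = 3), LUM rose by 1.06 and DCN by 0.67, and S100A4 fell by 1.87. Of 7 epithelial markers 3 fell and 1 rose (median -0.08, adjusted p = 0.461). KRT19 fell by 1.23, CLDN4 by 1.04 and KRT18 by 0.52, and EPCAM rose from 0.156 ± 0.11 to 0.662 ± 0.214 CPM, a call lost without mimic replicate 1 or 2 (adjusted p = 0.0504 and 0.0577). Of 6 endothelial markers 2 fell and 1 rose (median -0.31, adjusted p = 0.399), with ROBO4 lower by a log2 value of -2.32, TIE1 at -1.39, EGFL7 at 0.75 and ESAM at 0.89 (adjusted p = 0.16). The sign of that median rested on single libraries, at 0.06, 0.03 and 0.08 without control replicate 1, 2 or 3 and 0.08 without mimic replicate 2, and the epithelial median was 0.03 without control replicate 1, -0.18 without control replicate 3 and 0.57 with no filter. These counts were the same adjusted over the list alone. Of 5 leukocyte markers 2 fell and 0 rose (2 and 1 adjusted over the list alone), with a median of 0.52 and a mean of 0.27 but a downward test (adjusted p = 0.619), and the median was 0.34 without control replicate 2. CORO1A fell by 0.95 and CD68 by 0.81, while CD14 and CSF1R had log2 values of 1.61 and 0.52 (adjusted p = 0.0595 and 0.185). Of 9 neural markers 2 rose and 2 fell (3 and 3 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.663), which was 0.91 without control replicate 1, 0.03, 0.55 and 0.56 without mimic replicate 1, 2 or 3, and -0.43 with the CPM filter. MAP2 rose from 0.774 ± 0.191 to 3.99 ± 0.375 CPM and SYP from 0.374 ± 0.114 to 1.41 ± 0.172 CPM, while TUBB3 fell from 153.0 ± 21.1 to 94.98 ± 1.97 CPM and MBP fell by 1.17. Among long noncoding RNAs chosen after their values were seen, NEAT1, the scaffold of paraspeckles, rose from 283.8 ± 21.2 to 559.8 ± 21.5 CPM, MEG3 rose by 0.48, PURPL, a p53-regulated RNA, by 1.82 and H19 by 3.74 from 0.109 ± 0.05 CPM, and MALAT1 had a value of 0.22 (adjusted p = 0.268). CDKN2B, also chosen afterwards, had a value of -0.05 (adjusted p = 0.785).

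Genes with a match to the miR-340-5p seed lay lower, and GC content and 3' UTR length differ between genes with and without a match. A bias in either, or any motif of the same bases, could give such a shift, but against genes in the same length and GC cell the difference was -0.21, and 0 of the 104 rearrangements of the 7 bases gave one as low. A graded effect of the seed is consistent with matched medians of -0.20 with 1 match, -0.28 with 2 and -0.40 with 3 or more, the last resting on 38 genes. The matched difference ran from -0.20 to -0.23 with each library left out, where the unmatched one ran from -0.28 to -0.07. That the seed lowered these transcripts directly stays a hypothesis, since RNA levels 4 days after transfection cannot separate direct from secondary changes. In addition, 870 of the 2551 genes with a match had no matched cell.

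Genes close to silence in the control libraries rose, 24 of them to at least 1 CPM. Genomic DNA in the mimic libraries would raise silent genes at large, but summed CPM of 356 olfactory receptor genes stood at 2.25 ± 0.486 in the control group and 2.55 ± 0.408 in the mimic group (SD, n = 3), a ratio of 1.13. Neurons, a candidate source of NPY, BRINP3 and MAP2, would bring their abundant transcripts, but the sum of SNAP25, STMN2 and NEFM changed by -0.94 CPM, from 4.78 ± 0.909 to 3.84 ± 0.567 CPM, and STMN2 had 0 counts in every library. Nearly all of that sum was SNAP25, at 4.70 ± 0.919 and 3.45 ± 0.31 CPM, while NEFM went from 16 to 83 counts, so the sum argues only against neurons that would add 1 CPM or more to it, and a smaller share stays open, as does a change within the fibroblasts.

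The number of changed genes, 9696, could owe something to GC differences between libraries or to small structured RNAs that shift the scaling. With the GC correction 11779 genes passed, 9242 of them shared with the uncorrected test, and without small structured RNAs 9610 passed. The correction also raised the number of calls in simulation, from 104 to 144, so the higher count itself decides nothing. GC trends within a group add to its spread, and in that simulation 1.92% of the 104 uncorrected calls were false. The retained count therefore says little about trends within a group. The correction also takes out a GC trend between the groups. That 9242 genes stayed past the threshold argues against such a trend as the whole cause. The count of 9610 argues against small structured RNAs as the whole cause. An effect of the mimic as such, apart from its seed, stays open, since the control miRNA was the only other treatment.

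The 6 libraries allow 10 splits into groups of 3, so no share under 0.05 can be reached for any result. The real split gave 9696 genes, 22 lists, a G1/S median of 1.60, a G2/M median of 2.41, an LBR change of 1.95 and a matched seed difference of 0.213, all as sizes without sign, and the highest of the other splits gave 0, 17, 0.574, 0.765, 0.808 and 0.0981, so that for each of these 1 of the 10 splits, the real one, gave a result as large. Every other split mixes the groups, so it holds part of any group difference and adds the rest to the spread within groups. The smaller values of such splits are therefore no baseline without an effect. With 0 genes changed, they still had 14 to 17 lists past camera's threshold with the preset correlation. For the unmatched seed difference, 4 of the 10 splits gave one as large as the real 0.172, the highest being 0.241. The other 3 each set control replicate 1 and 2 mimic libraries against the rest. Control replicate 1 lies at an end of the GC trend of the control libraries. Matched on 3' UTR length and GC, those 3 splits gave 0.0981, 0.0762 and 0.0837, against 0.2231, 0.2409 and 0.2029 unmatched. Much of their unmatched difference therefore went with 3' UTR length or GC content. Whether the GC trend of the libraries gave it was not tested apart from length.

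A hypothesis formed after PDK4, BTG2, BCL2L11, BBC3 and BMF were seen to rise was that targets of the FOXO transcription factors may rise as a group. The test used a list of 24 other FOXO targets, written from memory before their values were seen. Of these, 22 were tested. Their median was 0.68, with 15 higher and 3 lower (camera p = 3.1e-06, and p = 0.00683 with an estimated correlation), and the median was 0.67 with the GC correction. FOXO1 itself rose from 0.166 ± 0.0521 to 2.28 ± 0.0854 CPM (SD, n = 3), DEPP1 rose by 2.18, CBLB by 1.88 and KLHL24 by 1.56, while CITED2 fell by 0.60, FOXO3 by 0.49 and PNPLA2 by 0.41. Several of these genes also answer to other regulators, so the test shows a shift of the list and not its cause. SOD2, CDKN1B and GADD45A, FOXO targets already in the fixed lists, were not in this list. SOD2 fell by 0.98 (SE 0.09), and CDKN1B and GADD45A did not pass (edgeR adjusted p = 0.385 and 0.107).

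LBR fell within the range of the G2/M list, whose members ran from -2.90 to -0.08, with 33 of the 53 lower than LBR at -1.95.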
